A study of Mus musculus with 15 samples.

How the data were processed

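The data are 15 bulk RNA-seq libraries of mouse liver taken at postnatal day 12, in 4 groups: C57 normoxia (n = 4), C57 hyperoxia (n = 4), BALBc normoxia (n = 3) and BALBc hyperoxia (n = 4). Per the labels, mice stayed in room air to day 7 and then in 75% oxygen or room air to day 12. RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra II kit. The authors deposited FPKM (fragments scaled by transcript length and library depth) for 54532 genes. Their processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse genome GRCm38, without stating every step. The strandedness of the libraries is not given in the sources used here. Raw reads and counts were not analysed here.

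Deposited values were matched to GENCODE M21 by gene identifier for symbol, biotype and position. Of the identifiers, 54409 matched and 123 did not. The unit was checked from the values themselves. Low values lay in steps of 1 fragment: 98.1% to 98.7% of the values under 30 fragments lay within 0.05 of a whole fragment, which gave the number of fragments behind each library's FPKM, 1.49e+07 to 1.91e+07. These steps also gave the number of genes at exactly 1 fragment, from which 2 classes of libraries were told apart at a boundary of 25% of the genes at 1 to 10 fragments. The class was defined from the data and is not a group of the study.

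Genes with an FPKM of at least 1 in at least 3 libraries were kept, which left 13026. Values were transformed as log2(FPKM + 1), with a pseudocount of 1. A linear model with 1 mean per group over all 15 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend. The 5 comparisons were hyperoxia against normoxia in C57, the same in BALBc, the difference of these responses (interaction), and BALBc against C57 in normoxia and in hyperoxia. P-values were adjusted within each comparison by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Means and SDs in the text are of FPKM, and log2 changes with their SE are from the model.

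Gene lists for liver metabolism, cell types and stress responses were fixed before the data were examined. There were 58 lists with 1157 symbols, of which 7 symbols had no match, and 55 lists had the minimum of 5 measured members. Each was tested with limma's camera, with a preset correlation between genes of 0.01. The same test with the correlation estimated from the data, and limma's fry, were run beside it. Camera compares a list with the other genes, whereas fry tests whether its genes move in 1 direction on balance. List p-values were adjusted over the 55 lists. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list.

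Genes named in the text were chosen by a rule fixed before the data were examined. Per comparison, the rule took the 8 largest changes in each direction among called protein-coding genes with a symbol and a mean FPKM of at least 2 in the higher group, and up to 4 members with the smallest p of each list described. Genes named for other reasons are said to be so, and some genes that the rule takes are not reported here.

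Because FPKM are not counts, count-based tests were not run. Replicate numbers are shared between groups, so pairing was checked from the values. Of 21 pairs with the same number 1 had a correlation above 0.1, and 4 of the 15 libraries correlated best with their own number, so the libraries were treated as unpaired and the number was used only as a block in an alternative. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, median scaling, quantile normalization, no variance trend, a replicate block, a covariate for Xist, array weights, only the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were library class as a term, a covariate for weakly expressed genes, only the 7 or the 8 libraries of 1 class, and leaving out features likely to share reads.

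The model was tested on simulated data by multiplying or dividing FPKM + 1 of 200 genes in 5 simulations per comparison. At 2-fold, 78.2% of such genes were recovered in C57, 77.9% in BALBc, 54.3% for the interaction, 77% between strains in normoxia and 81.2% in hyperoxia. At 1.5-fold the recovery was 42.4%, 44.5%, 20%, 45.7% and 47.8%, so smaller changes are often missed at this number of libraries. The same fold of FPKM alone is a smaller step on this scale for weakly expressed genes, whose recovery may be lower. The share of false calls was 10.9%, 3.37%, 7.73%, 17.7% and 0.811%, above the nominal 5% in 3 of the comparisons. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.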

Results

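Liver RNA in 15 mouse libraries was sequenced at postnatal day 12. The samples come from 2 strains used in studies of oxygen-induced retinopathy, in which young mice kept in high oxygen lose retinal capillaries. The series describes C57 as susceptible and BALBc as resistant. Hyperoxia groups breathed 75% oxygen from postnatal day 7 to day 12, and normoxia groups breathed room air. There were 4 C57 normoxia, 4 C57 hyperoxia, 3 BALBc normoxia and 4 BALBc hyperoxia libraries. The stated aim was to compare liver metabolism between the resistant and the susceptible strain.

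Expression was measured as FPKM for 54532 genes. The steps between the values of weakly expressed genes gave a denominator of 1.49e+07 to 1.91e+07 fragments per library. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical in part. Each group held libraries with and without an Xist level above an FPKM of 1, so no group came from a single animal. Genes of near-identical families (Serpina3, Serpina1, Mug, Mup, Cyp2c, Cyp4a and Cyp2a genes, Hamp and Hamp2, Eno1b and its pseudogene copy, ribosomal protein genes and their pseudogene copies) are uncertain, since the authors' counting could have divided shared reads between members.

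The libraries fell into 2 classes that the labels do not name. In 7 libraries, 29.9% to 33.7% of the genes at 1 to 10 fragments sat at exactly 1 fragment. These were all 4 C57 hyperoxia libraries, C57 normoxia 4, BALBc normoxia 1 and BALBc hyperoxia 1. In the other 8 libraries the value was 10.3% to 18.4%. The class with many such genes had more genes above 0, 21216 to 21829 in its C57 libraries against 16011 to 17287 in the other C57 libraries. The class overlapped with oxygen in C57, where 4 of 4 hyperoxia libraries but 1 of 4 normoxia libraries had many such genes. In C57 normoxia 2, 68 genes sat at 3 fragments and 178 at 14, against 888 and 125 in C57 hyperoxia 1. C57 normoxia 3 and C57 hyperoxia 4 had the same denominator, 1.613e+07 fragments, but 1844 and 6706 genes at 1 to 10 fragments. Like denominators thus do not mean that weakly expressed genes were seen alike.

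**Figure D1:**
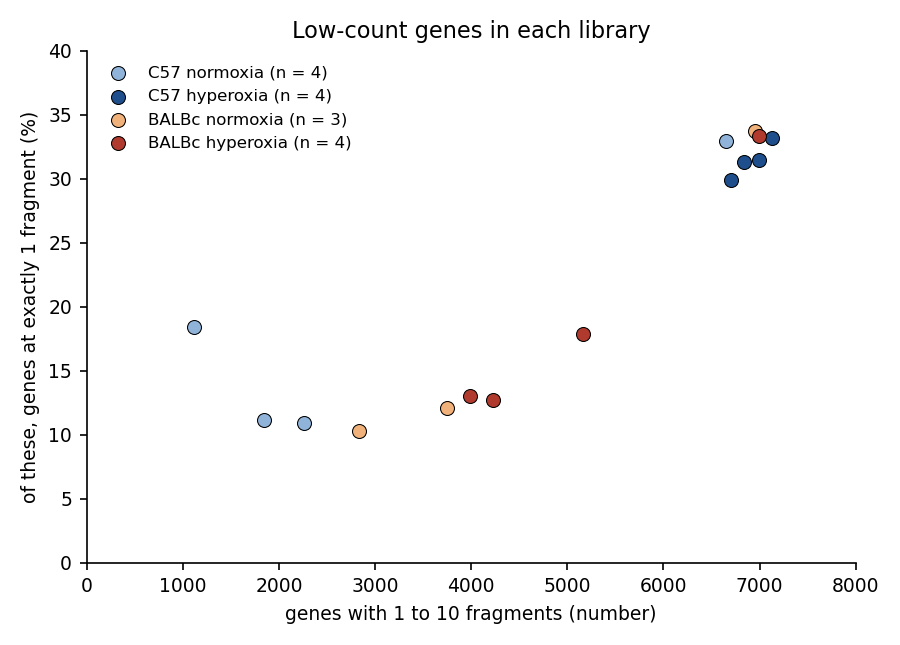
Number of genes at 1 to 10 fragments (x axis) and percent of these that sat at exactly 1 fragment (y axis), with 1 point per library, coloured by group. The 7 libraries with many such genes lie between 29.9% and 33.7%, and the other 8 between 10.3% and 18.4%.

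The comparison within C57 asked how livers of the susceptible strain differed after hyperoxia. Several macrophage genes fell. Marco, a macrophage scavenger receptor, averaged 226.5 ± 62.5 FPKM (mean ± SD, n = 4) in normoxia and 49.8 ± 21.4 (n = 4) in hyperoxia, and Lyz2, a lysozyme of myeloid cells, averaged 138 ± 19.9 and 57.5 ± 10.2. Aldoa and Tpi1, enzymes of glycolysis, fell, as did Hmox1, a haem-degrading enzyme and a target of hypoxia-inducible factor, the transcription factor active in low oxygen. Hamp, which encodes the iron-regulating hormone hepcidin, rose from 21.8 ± 9.71 to 124 ± 63.7 FPKM.

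Of 13026 genes tested with limma and Benjamini-Hochberg adjustment, 122 passed an adjusted p of 0.05 in C57. Of these, 29 were higher and 93 lower in hyperoxia, and 19 differed by at least 2-fold. Serpina3k (ENSMUSG00000058207, GRCm38 chromosome 12, 104338486 to 104346144), a serine protease inhibitor gene of a near-identical family, had the largest rise among the named genes, a log2 change of 2.68 ± 0.39 (SE, adjusted p = 0.00522). Hamp (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032) rose by 2.45 ± 0.51 (adjusted p = 0.0393), with 8.49 to 31.8 FPKM in normoxia and 59.7 to 212 in hyperoxia. Its neighbour Hamp2 rose by 1.92 (adjusted p = 0.045). Mug2 and Mug1, genes of plasma protease inhibitors, rose by 1.27 and 1.06, and the carboxylesterase Ces3a by 0.73, and Rnf125, a ubiquitin ligase, rose from 17.9 to 36.7 FPKM.

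Among the genes that fell in C57, Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024) changed by -2.21 ± 0.25 (adjusted p = 0.00225), with all 4 hyperoxia libraries (30.9 to 79.9 FPKM) below all 4 normoxia libraries (182 to 316 FPKM). Lyz2 changed by -1.26, Tlr2, a receptor for bacterial lipoproteins, by -1.23, the macrophage lectin Cd209f by -1.06, and Ncf4, a subunit of the phagocyte oxidase, by -0.93. Fabp4, a fatty acid binding protein of fat cells and macrophages, changed by -1.06, the aldo-keto reductase Akr1b7 by -1.14, and the protease inhibitor Serpina3g by -0.88.

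Of 20 measured Kupffer cell and macrophage markers, 1 rose and 4 fell in C57 (adjusted over the list alone, 1 rose and 10 fell), with a median log2 change of -0.33. Besides Marco and Lyz2, the haem-degrading enzyme Hmox1 (-0.84) and Spic, a transcription factor of iron-recycling macrophages (-0.81), fell. The Kupffer cell lectin Clec4f, picked out after its value was seen, rose by 0.44. The list was called lower (camera adjusted p = 2.49e-05), a call lost with an adjusted p = 0.607 with an estimated correlation. Of 22 hypoxia-inducible factor targets, 2 fell, Hmox1 and the adenylate kinase Ak4 (-0.51), and 10 fell when adjusted over the list alone. That list had a median of -0.38 and stayed called (camera adjusted p = 2.7e-07; adjusted p = 0.00265 with an estimated correlation). Its member Tfrc, the transferrin receptor, had a log2 change of -0.78 that did not pass (adjusted p = 0.0819).

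Of 23 glycolysis and glycogen genes, 6 fell in C57, including Aldoa (-0.66), Tpi1 (-0.44), Eno1 (-0.47) and Gpi1 (-0.45); adjusted over the list alone, 7 fell and 2 rose. The list was called lower (adjusted p = 9.59e-06; adjusted p = 0.066 with an estimated correlation). Of 19 genes of peroxisomal and microsomal fatty acid oxidation, 1 fell, the fatty acid hydroxylase Cyp4a14 (-0.59), and adjusted over the list alone 8 fell and 1 rose. Cyp4a10 had a change of -0.99 that did not pass (adjusted p = 0.0614). The list had a median of -0.16 and was called lower (camera adjusted p = 0.00254), a call lost under quantile normalization (adjusted p = 0.0992). Of 26 erythroid markers none passed over all genes, 3 were lower adjusted over the list alone, and 24 had values below 0 (adjusted p = 0.000172). Of 17 inflammatory genes, Nfkbia, the inhibitor of NF-kB, fell by 0.71 (list adjusted p = 0.00208; adjusted p = 0.546 with an estimated correlation). Of 29 interferon-stimulated genes, the transcription factor Irf7 rose by 0.69, and adjusted over the list alone 4 rose (list adjusted p = 0.000184). No cell cycle gene of 40 passed, over all genes or adjusted over the list alone, yet 37 had values above 0 and the list was called higher (median 0.21, adjusted p = 9.59e-06). Cholesterol synthesis was called higher with a median of 0.16 and 0 of 24 genes passing (adjusted p = 0.011). For the fatty acid oxidation, erythroid, interferon, cell cycle and cholesterol lists, the call was lost with an adjusted p = 0.607 with an estimated correlation. The C57 hyperoxia libraries were all of the class with many genes at 1 fragment, and this holds for each of these groups.

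In all, 14 of 55 lists were called in C57, 3 higher and 11 lower, and 1 of them, the hypoxia-inducible factor targets, with an estimated correlation; fry called 2. The others called lower were periportal hepatocyte genes (adjusted p = 0.0128), fetal and neonatal liver genes (0.0185), gluconeogenesis (0.0268), antioxidant enzymes (0.035) and the nuclear-encoded respiratory chain (0.00307), each with an adjusted p = 0.607 with an estimated correlation. Gluconeogenesis also lost its call under quantile normalization (camera adjusted p = 0.272). Without C57 normoxia 4 the erythroid and respiratory chain lists lost their calls (highest adjusted p = 0.117 and 0.509), as did cholesterol synthesis without C57 normoxia 2 or 4 or hyperoxia 2 (0.149), periportal genes without C57 normoxia 4 or hyperoxia 3 (0.151), fetal genes and gluconeogenesis without C57 normoxia 1 or 4 or hyperoxia 2 (0.115 and 0.107), and antioxidant enzymes without C57 normoxia 3 or 4 or hyperoxia 1 or 3 (0.58).

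With library class as a term in the limma model 14 C57 genes passed, with a covariate for weakly expressed genes 12, and among only the 7 libraries with many genes at 1 fragment, which leave 1 C57 normoxia library, 0. The C57 count was 62 without C57 normoxia 2, 237 without C57 normoxia 4, 36, 46, 46 and 45 without C57 hyperoxia 1, 2, 3 and 4, 76 without BALBc normoxia 2 and 75 without BALBc hyperoxia 3. Of 35 called genes that the naming rule takes, 19 passed whichever library was left out, among them Marco, Lyz2, Serpina3k and Aldoa, whereas Hamp lost its call in 9 of the 15 refits, Hamp2 in 12, Ces3a in 9, Ak4 in 11, Cyp4a14 in 13, Nfkbia in 11, Cd209f in 5, Irf7 in 4 and Serpina3g in 3.

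The comparison within BALBc asked the same of the resistant strain. The largest rises among the named genes were those of Hamp and its neighbour Hamp2. Hamp rose from 1.74 ± 0.83 FPKM (n = 3) in normoxia to 257 ± 127 (n = 4) in hyperoxia, and Tfrc, the transferrin receptor that takes up iron, fell from 45.2 ± 1.78 to 15.8 ± 5.4 FPKM. Nsdhl, Idi1 and Sqle, enzymes of cholesterol synthesis, rose, as did Ppbp and Itga2b, genes of platelets and their precursors. Cps1, the first enzyme of the urea cycle, fell, as did Cyp2f2, a gene of periportal hepatocytes, the cells near the portal vein. Thrsp, which promotes fatty acid synthesis, fell from 9.08 ± 1.17 to 2.02 ± 0.117 FPKM.

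In BALBc 123 genes passed, 53 higher and 70 lower in hyperoxia, 32 of them by at least 2-fold. Hamp rose by 6.36 ± 0.55 on the log2 scale (adjusted p = 0.000143). Its values were 1.11 to 2.68 FPKM in normoxia and 67.8 to 339 in hyperoxia, BALBc hyperoxia 1 having the lowest. Hamp2 (ENSMUSG00000056978, chromosome 7, 30922372 to 30924681) rose by 3.47 ± 0.45 (adjusted p = 0.00248). Igfbp1, an insulin-like growth factor binding protein (ENSMUSG00000020429, chromosome 11, 7197782 to 7202546), rose from 72.6 ± 30.7 to 198 ± 22.3 FPKM (log2 change 1.52 ± 0.23, adjusted p = 0.00623). Inhbb, an activin subunit, rose by 1.32, Id1, a target of bone morphogenetic protein signalling, by 1.29, and Ankrd55 by 1.28.

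Among the genes that fell in BALBc, Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730) fell with an adjusted p of 0.000239, and Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794) changed by -1.51 ± 0.21 (adjusted p = 0.00378). The cytochrome P450 gene Cyp2c39 changed by -1.30 and Cyp2a5 fell from 23.4 to 9.76 FPKM, Baat, which conjugates bile acids to amino acids, changed by -1.27, Mug1 by -1.26, and Rgs5, a regulator of G protein signalling in pericytes, by -1.21.

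Of 27 iron and haem genes, 4 rose (Hamp, Hamp2, Id1 and the biliverdin reductase Blvrb, 0.47) and 1 fell, Tfrc; adjusted over the list alone 8 rose and 3 fell. Blvrb was picked out here after its value was seen. As a list they were not called (camera adjusted p = 0.0669). Of 24 cholesterol synthesis genes, 4 rose, namely Nsdhl (0.87), Idi1 (1.11), Sqle (1.10) and Hmgcs1 (0.66), and adjusted over the list alone 15 rose and 1 fell. The list had a median of 0.38 (adjusted p = 3.05e-12; adjusted p = 0.116 with an estimated correlation). Of 9 megakaryocyte and platelet markers 4 rose, the integrin Itga2b (0.73), the chemokines Ppbp (7.68 to 19.9 FPKM) and Pf4 (0.98), and the tubulin Tubb1 (1.32), and 6 rose adjusted over the list alone. Their median was 0.73 (adjusted p = 3.96e-08; adjusted p = 0.0224 with an estimated correlation). Of 19 genes of peroxisomal and microsomal fatty acid oxidation 2 rose, including Cyp4a32 (1.11), and adjusted over the list alone 10 rose (adjusted p = 6.05e-07; adjusted p = 0.107 with an estimated correlation). Of 15 genes listed for polyunsaturated fatty acid desaturation and elongation, the acyl-CoA thioesterases Acot2 (0.61) and Acot1 (0.68) and the desaturase Fads1 (0.39) rose, 4 adjusted over the list alone (camera adjusted p = 0.00017, and adjusted p = 0.107 with an estimated correlation). Acot2 and Acot1 themselves neither desaturate nor elongate fatty acids. Pdk4, which limits glucose oxidation, rose by 0.97 as 1 of 20 ketogenesis and PPARA-regulated genes (list adjusted p = 0.0191; adjusted p = 0.387 with an estimated correlation; 0.297 without BALBc normoxia 3).

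Of 24 periportal hepatocyte genes 5 fell in BALBc, among them Tdo2 (-0.78), Cyp2f2 (-1.01), Cps1 (-0.89) and Uox (-0.56), and adjusted over the list alone 14 fell (median -0.42, adjusted p = 1.77e-10). Of 17 urea cycle genes only Cps1, the enzyme of the first step, fell over all genes, and 10 fell adjusted over the list alone (median -0.44, adjusted p = 2.38e-09). For both lists the call was lost with an adjusted p = 0.107 with an estimated correlation. The calls were not limited to periportal genes, since pericentral genes (2 of 25 fell, median -0.20, adjusted p = 0.00347; adjusted p = 0.275 with an estimated correlation) and general hepatocyte markers (1 of 20 fell, median -0.12, adjusted p = 0.00017; adjusted p = 0.216 with an estimated correlation) were also called lower. Of 28 amino acid catabolism genes 4 fell, Haao (-0.59), Tdo2, Hgd (-0.46) and Hpd (-0.52), 10 adjusted over the list alone (adjusted p = 2.49e-07; adjusted p = 0.216 with an estimated correlation). Of 16 cytosolic heat shock genes Hsp90aa1 fell by 0.53, and 5 fell adjusted over the list alone (adjusted p = 3.34e-06; adjusted p = 0.0224 with an estimated correlation). Of 20 endoplasmic reticulum chaperones Pdia6 fell by 0.39, and 8 fell adjusted over the list alone (adjusted p = 4.82e-06; adjusted p = 0.216 with an estimated correlation). Of 25 targets of the xenobiotic receptors CAR and PXR, Sult2a1 (-1.17), Cyp2c39 and Cyp2a5 fell, 7 fell and 3 rose adjusted over the list alone, and the list was called lower (adjusted p = 0.00199; adjusted p = 0.199 with an estimated correlation). Of 13 mitochondrial genome transcripts mt-Cytb (-0.88), mt-Nd5 (-0.60) and mt-Nd6 (-0.65) fell, 6 adjusted over the list alone (adjusted p = 1.81e-06; adjusted p = 0.275 with an estimated correlation). Of 22 hypoxia-inducible factor targets Igfbp1 rose and Tfrc fell, and the list was not called (adjusted p = 0.78), its median of 0.06 and its mean of -0.00111 differing in sign.

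In all, 29 of 55 lists were called in BALBc, 12 higher and 17 lower, and 2 of them with an estimated correlation, the platelet markers and the cytosolic heat shock genes; fry called 18. Of the others, erythroid markers were called higher (median 0.42, adjusted p = 2.75e-05; adjusted p = 0.33 with an estimated correlation), though their only called gene, Tfrc, fell. Genes of growth hormone and insulin-like growth factor signalling were also called higher (adjusted p = 0.0127; adjusted p = 0.107 with an estimated correlation), with Igfbp1 and Igfbp2 (1.12) rising. Glycolysis and glycogen genes were called lower (median -0.19, adjusted p = 0.000554; adjusted p = 0.107 with an estimated correlation).

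The BALBc count was 53 without BALBc normoxia 2, 24 without BALBc normoxia 3, and 69, 56, 63 and 66 without BALBc hyperoxia 1, 2, 3 and 4. Among the 8 libraries with few genes at 1 fragment it was 12, with 2 normoxia and 3 hyperoxia libraries of BALBc. Of 57 called genes that the naming rule takes, 13 passed whichever library was left out, among them Hamp, Hamp2, Igfbp1, Tfrc, Thrsp and Mug1, whereas Tubb1 and Cyp2a5 each lost their call in 12 of 15 refits, Acot1 in 13, Pf4 in 10, Hmgcs1 and Fads1 in 8, Nsdhl, Sqle and Pdk4 in 6 and Cps1 in 5.

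**Figure D2:**
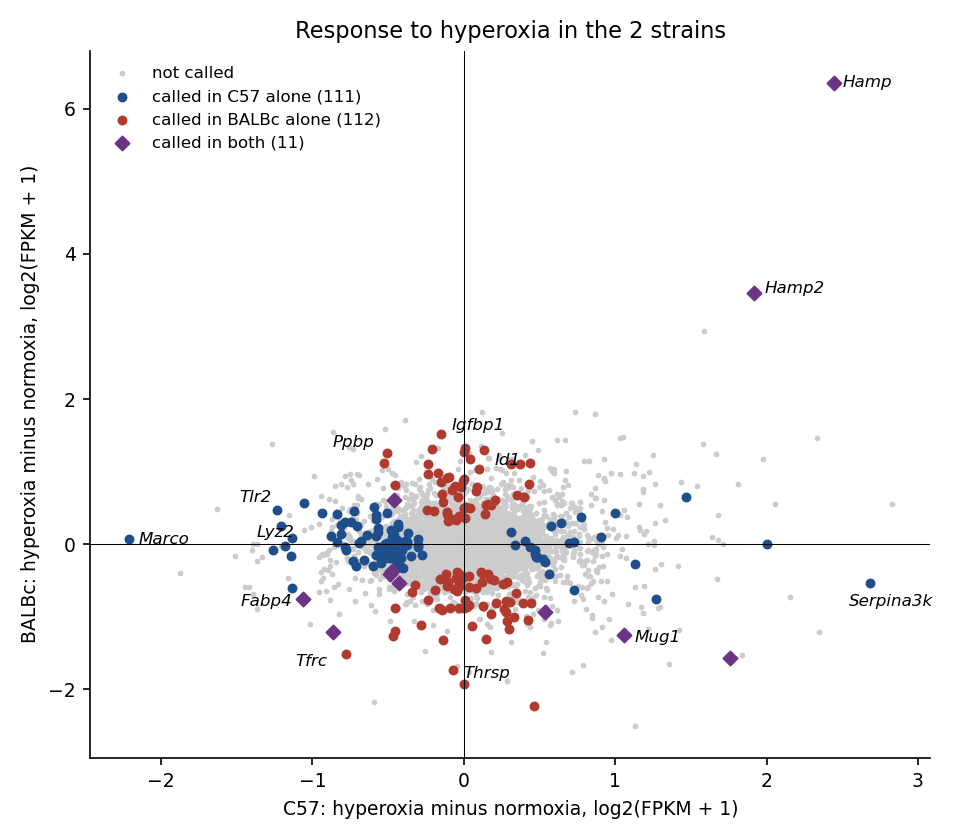
Log2 change after hyperoxia in C57 (x axis) and in BALBc (y axis) for each of the 13026 tested genes. Colours mark the 111 genes called in C57 alone, the 112 in BALBc alone and the 11 in both; Pearson's r over all points was 0.0335, with a jackknife SE over libraries of 0.0948.

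The test of the interaction asked which genes responded differently in the 2 strains. Values are the BALBc response minus the C57 response. Hamp rose in both strains and rose more in BALBc. Mug1 and the cytochrome P450 gene Cyp2c70 rose in C57 and fell in BALBc. The fatty acid hydroxylases Cyp4a10 and Cyp4a14 and the platelet chemokine Ppbp had a higher response in BALBc. For the macrophage genes Marco and Lyz2 the difference came from their fall in C57, as neither passed in BALBc. Both started lower there, and Lyz2 lay at 24.2 to 39 FPKM in BALBc normoxia and 26.9 to 29.6 in BALBc hyperoxia. The urea cycle enzyme Cps1 and the mitochondrial transcripts mt-Cytb and mt-Nd5 had a lower response in BALBc. The share of fragments from the mitochondrial genome also varied with library class.

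The interaction test called 107 genes, 49 with a higher and 58 with a lower response in BALBc, 56 of them by at least 2-fold. Hamp differed by 3.91 ± 0.75 (limma adjusted p = 0.0277), a difference that cannot be told from the lower starting level of BALBc. Afp, alpha-fetoprotein, differed by 2.65 ± 0.47 (adjusted p = 0.021); its means were 626 and 292 FPKM in C57 normoxia and hyperoxia and 16.3 and 43.3 in BALBc, neither change passing alone (adjusted p = 0.0867 and 0.0812). Marco differed by 2.28 ± 0.36 (adjusted p = 0.0144), its BALBc means being 7.13 ± 0.82 in normoxia and 7.61 ± 1.86 in hyperoxia, and Tlr2 by 1.70. Ppbp and Igfbp1 differed by 1.76 and 1.67.

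Among the lower responses, Mug1 differed by -2.32 ± 0.22 (adjusted p = 0.00025); Mug1 averaged 18.7 FPKM in C57 normoxia, and 132 and 53.9 in BALBc normoxia and hyperoxia. Cyp2c70, which makes muricholic bile acids, differed by -1.48 ± 0.16 (adjusted p = 0.00105), with changes of 0.54 in C57 and -0.94 in BALBc. Serpina3k differed by -3.21, Mug2 by -2.02, Cyp4f14 by -1.99, Thrsp by -1.66 and Prodh, a proline dehydrogenase, by -1.47. Thrsp lay at 0 to 0.708 FPKM in C57 normoxia and at 0.0861 to 0.453 in C57 hyperoxia. It thus had almost no room to fall in C57, and its difference cannot be told from the lower starting level of C57.

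Of 19 genes of peroxisomal and microsomal fatty acid oxidation, 3 had a higher response in BALBc, the hydroxylases Cyp4a10 (1.93) and Cyp4a14 (1.10) and the thioesterase Acot3 (1.72), and 12 adjusted over the list alone. Cyp4a10 averaged 89.2 ± 22.3 and 46.2 ± 17.9 FPKM in C57 normoxia and hyperoxia and 71.3 ± 10.9 and 137 ± 10.8 in BALBc, and Acot3 averaged 10.9 and 6.04 in C57 and 12.1 and 23.1 in BALBc. The list had a median of 0.40 (adjusted p = 4.81e-08; adjusted p = 0.108 with an estimated correlation). Among 15 genes listed for polyunsaturated fatty acid desaturation and elongation the thioesterase Acot2 differed by 1.07, and 4 differed adjusted over the list alone (camera adjusted p = 0.000736, and adjusted p = 0.108 with an estimated correlation). No gene of the cholesterol list passed over all genes, 2 did adjusted over the list alone, and the list was called higher (median 0.25, adjusted p = 0.000637; adjusted p = 0.358 with an estimated correlation).

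Of 9 platelet markers Ppbp passed over all genes, and 6 were higher adjusted over the list alone (median 0.70, adjusted p = 1.45e-07; adjusted p = 0.0226 with an estimated correlation). Of 22 hypoxia-inducible factor targets, Hmox1 (1.26), Ak4 (0.93) and Igfbp1 had a higher response in BALBc, 6 adjusted over the list alone (median 0.18, adjusted p = 0.000189; adjusted p = 0.0226 with an estimated correlation). Of 26 erythroid markers Rhd, a blood group protein, differed by 1.31, and 7 differed adjusted over the list alone (median 0.59, adjusted p = 4.81e-08; adjusted p = 0.25 with an estimated correlation). Of 20 Kupffer cell and macrophage markers 4 had a higher response in BALBc, Hmox1, Marco, Lyz2 (1.18) and Spic (0.95), each of which had fallen in C57. Adjusted over the list alone 8 were higher and 1 lower (camera adjusted p = 5.59e-06, and adjusted p = 0.254 with an estimated correlation). None of 17 inflammatory genes passed over all genes, and 7 were higher adjusted over the list alone (median 0.40, adjusted p = 1.53e-05; adjusted p = 0.108 with an estimated correlation). Of 14 fetal and neonatal liver genes Afp and the imprinted gene Peg3 (1.01) were higher, with a list median of 0.47 (adjusted p = 0.000456; adjusted p = 0.194 with an estimated correlation). Iron and haem genes had 3 higher of 27, Hamp, Hmox1 and Blvrb (0.72), and the list was called higher (adjusted p = 0.0212; adjusted p = 0.186 with an estimated correlation; 0.0501 without BALBc normoxia 3).

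Of 17 urea cycle genes Cps1 had a lower response in BALBc (-1.16), and 7 were lower adjusted over the list alone (median -0.51, adjusted p = 4.94e-07; adjusted p = 0.186 with an estimated correlation). Of 13 mitochondrial genome transcripts mt-Cytb (-0.85) and mt-Nd5 (-0.68) were lower, 6 adjusted over the list alone (median -0.68, camera adjusted p = 5.36e-07, and adjusted p = 0.257 with an estimated correlation). The mitochondrial genome held 5.50% of fragments in C57 normoxia 4, the library with many genes at 1 fragment, and 3.90% to 4.37% in the other C57 normoxia libraries. It held 4.24% to 4.94% in C57 hyperoxia, where all libraries were of that class. Library class may thus account for part of this difference. None of 40 cell cycle genes passed, over all genes or adjusted over the list alone, with 37 values below 0 (median -0.28, adjusted p = 5.59e-06; adjusted p = 0.335 with an estimated correlation). In all, 31 of 55 lists were called, 16 higher and 15 lower, and 2 of them, the platelet markers and the hypoxia-inducible factor targets, with an estimated correlation; fry called 11.

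**Figure D3:**
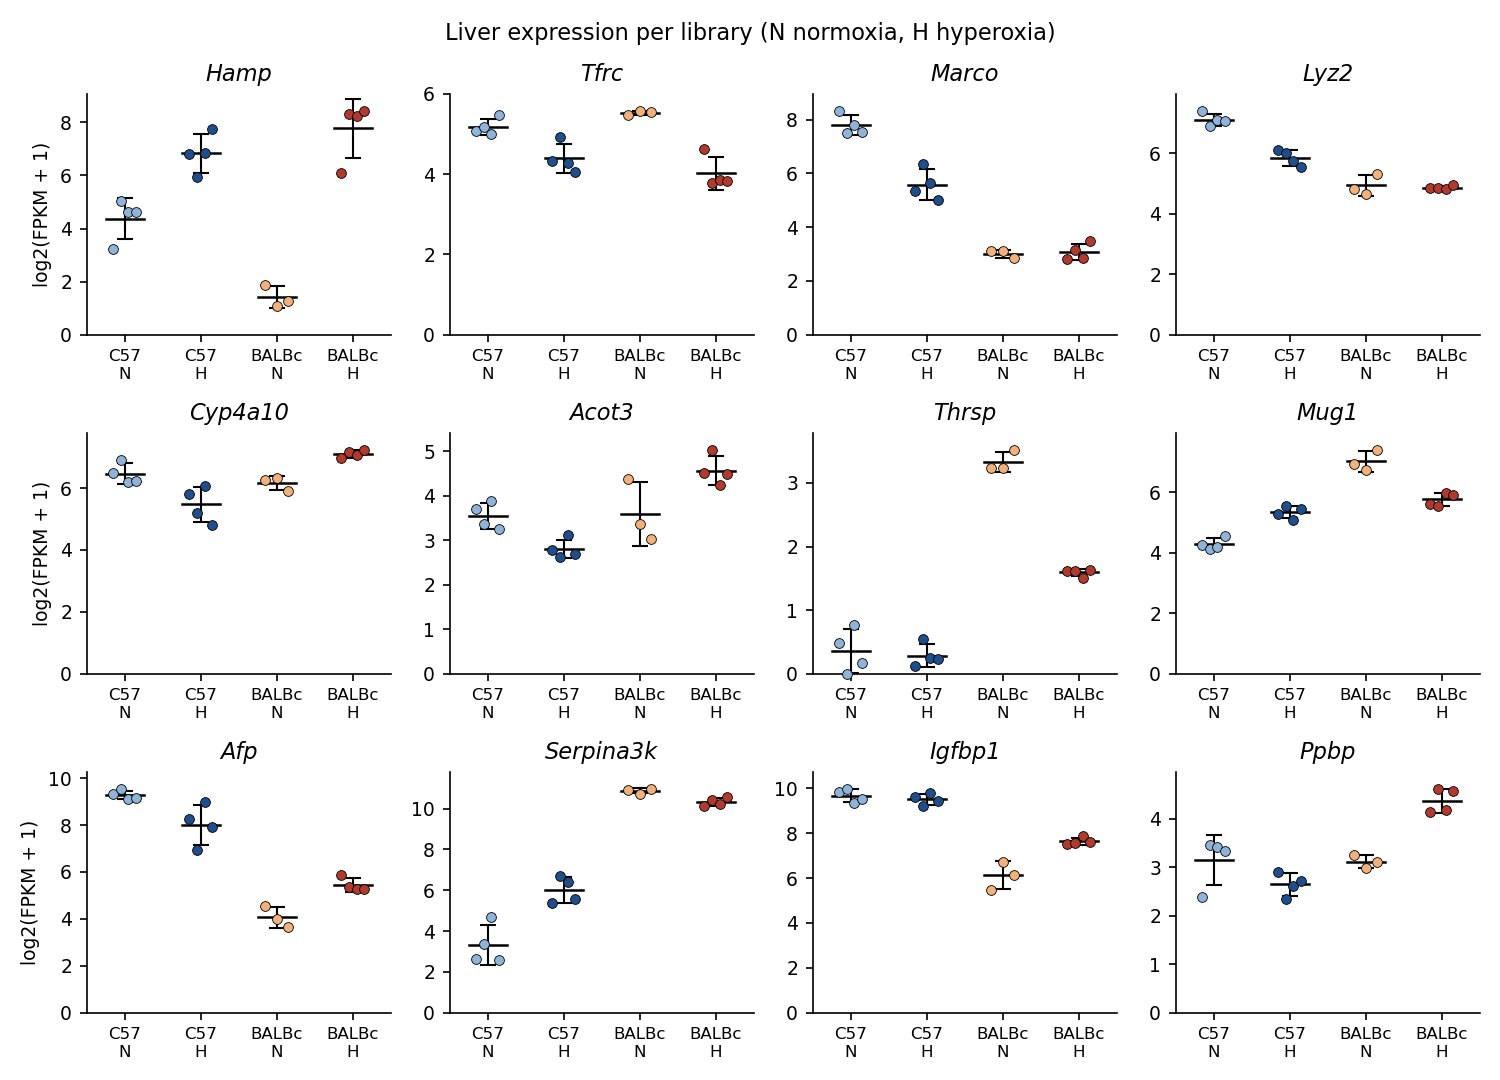
Expression of 12 genes as log2(FPKM + 1) (y axis) in the 4 groups (x axis: C57 or BALBc, N normoxia, H hyperoxia). Points are libraries, the wide line is the mean and the bars are the SD of the log2 values; Hamp lies at 1.11 to 2.68 FPKM in BALBc normoxia and at 67.8 to 339 in BALBc hyperoxia.

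**Figure D4:**
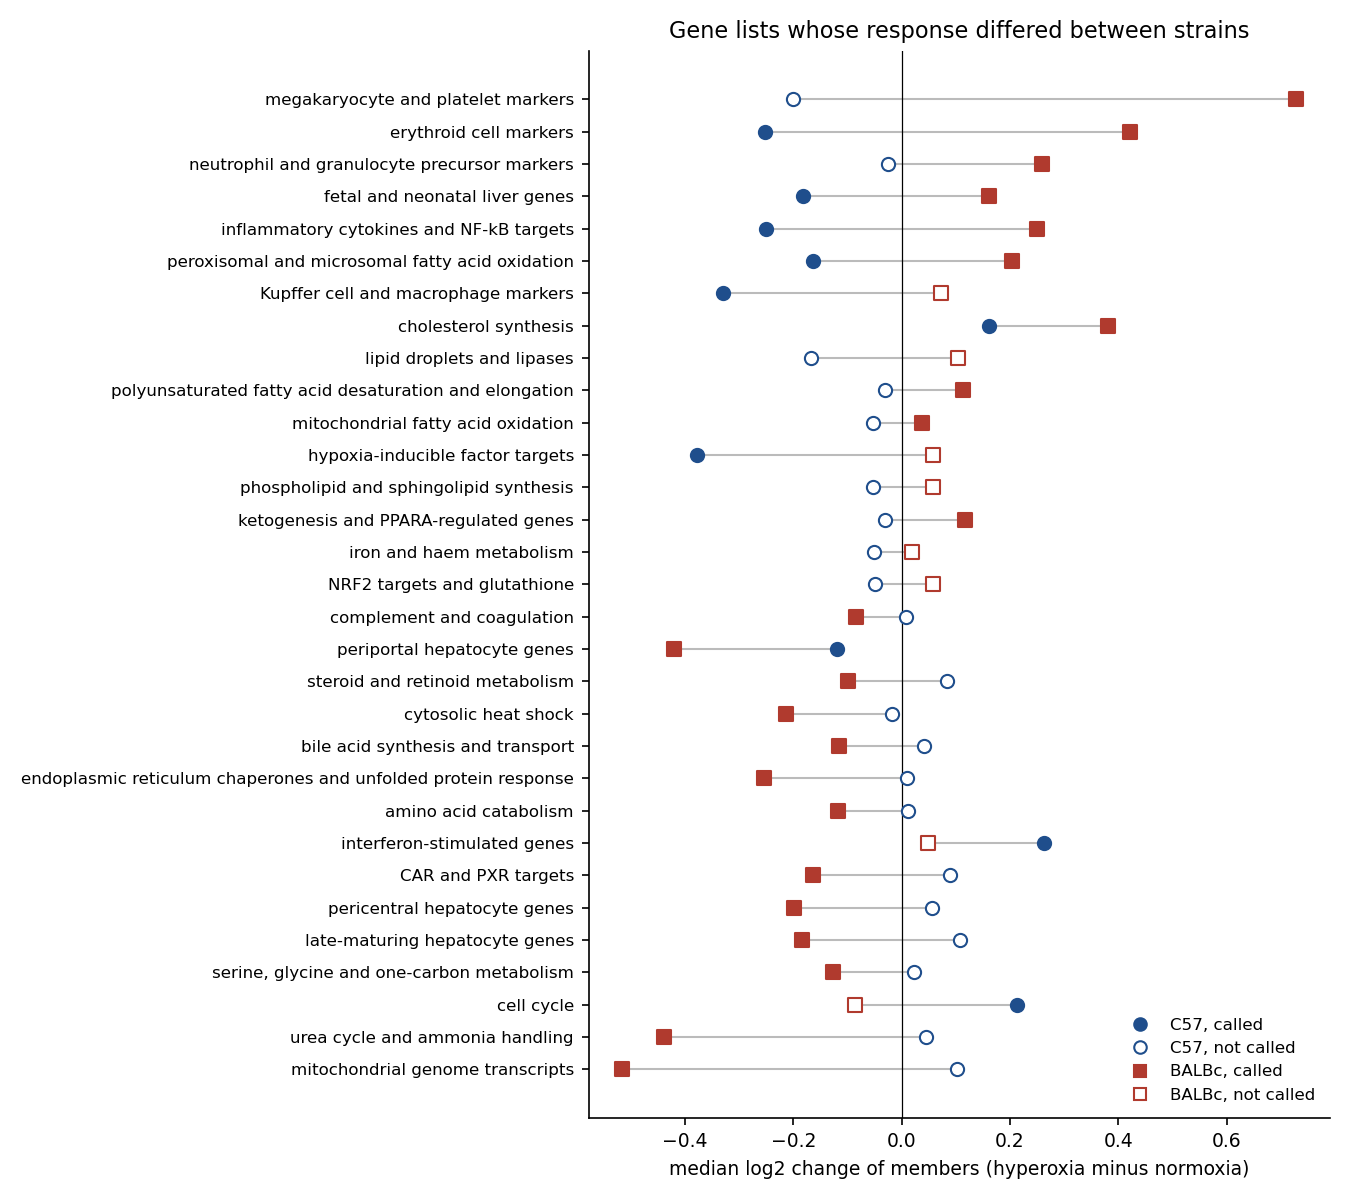
Median log2 change after hyperoxia (x axis) of the members of each of the 31 gene lists (y axis) called in the interaction test, in C57 (circles) and BALBc (squares). Filled symbols mark lists called within that strain; the platelet markers lie at 0.73 in BALBc and the hypoxia-inducible factor targets at -0.38 in C57.

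Across the 13026 genes the changes in the 2 strains had a Pearson's r of 0.0335 (jackknife SE over libraries 0.0948) and a Spearman's rho of 0.022; genes are not independent replicates. Both strains raised Hamp and Hamp2, 2 genes where independent lists would share 0.118, and lowered Rnase4, Atp5k, Eno1, Rgs5 and Fabp4, 5 genes where 0.5 would be shared. There were 3 genes higher in C57 and lower in BALBc, Mug1 and Cyp2c70 among them, where 0.156 would be shared, and Acot2 was lower in C57 and higher in BALBc, where 0.378 would be shared. Rnase4, Atp5k and Acot2 were named for falling in these small counts, after their values were seen.

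With library class as a term in the limma model 28 genes passed the interaction test, and with a covariate for weakly expressed genes 17. The interaction count was 162 without C57 normoxia 4, 45 and 53 without C57 hyperoxia 2 and 4, 47 and 44 without BALBc normoxia 2 and 3, and 40, 50 and 48 without BALBc hyperoxia 2, 3 and 4. Of 44 called genes that the naming rule takes, 15 passed whichever library was left out, among them Mug1, Mug2, Cyp2c70, Marco, Tlr2, Thrsp and Hmox1, whereas Hamp lost its call in 8 of 15 refits, Igfbp1 in 7, Acot3, Rhd and mt-Nd5 in 12, Spic in 13, Peg3 in 11 and Cps1 in 7, Afp and Cyp4f14 without BALBc normoxia 2 or 3, Cyp4a10, Serpina3k and Prodh without BALBc normoxia 3, and Ppbp without BALBc normoxia 2.

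The comparison of the strains in room air asked how livers of the resistant and susceptible strain differed without oxygen exposure. BALBc livers expressed less of several genes of the fetal liver and of macrophages. Afp, the main fetal plasma protein, averaged 626 ± 81.9 FPKM (n = 4) in C57 and 16.3 ± 5.57 (n = 3) in BALBc, and Marco averaged 226.5 ± 62.5 and 7.13 ± 0.82. They expressed more of Fabp1, the liver fatty acid binding protein, and of the lipase Mgll. Hamp was lower in BALBc, with means of 21.8 in C57 and 1.74 in BALBc.

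Here 3910 genes passed, 2006 higher and 1904 lower in BALBc, 704 of them by at least 2-fold. Serpina3k was higher by 7.55 ± 0.42 (adjusted p = 6.44e-09), with 11.1 ± 9.43 FPKM in C57 and 1877 ± 155 in BALBc. Cyp2b10, a drug-inducible cytochrome P450, was higher by 4.36 (32.9 ± 4.16 FPKM in BALBc), the eosinophil protein gene Prg2 by 3.73, Eno1b by 3.63, Cyp2c39 by 3.59, the complement protease gene C1s2 by 3.09, Prodh by 3.07 and Thrsp by 2.97. Marco was lower, at -4.77 ± 0.27 (adjusted p = 6.58e-09), as were Afp at -5.22 ± 0.35 (adjusted p = 4.62e-08) and the steroid dehydrogenase gene Akr1c18 at -4.55.

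The ribosomal protein genes Rpl29 (-6.41), Rps18 (-5.73), Rpl26 (-5.70), Rps2 (-5.42) and Rpl30 (-4.17) were also lower in BALBc. Rpl29 averaged 146 ± 8.79 FPKM in C57 and 0.753 ± 0.337 in BALBc. Of 83 ribosomal protein genes 74 were lower and 0 higher in limma, with a median of -0.78. Of the 7 that were at least 4-fold lower, annotated pseudogene copies of 5 gained signal in BALBc and those of 2 did not, with a median gain over the 7 genes of 0.124 of the parent gene's C57 level.

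Of 14 fetal and neonatal liver genes 11 were lower in BALBc, including Gpc3 (-2.54), Afp, the imprinted RNA H19 (-2.35) and the growth factor Igf2 (-3.06), and 1 was higher, the neonatal cytochrome P450 Cyp3a16, with the same counts adjusted over the list alone (median -0.94, adjusted p = 8.52e-06; adjusted p = 0.236 with an estimated correlation). Of 20 Kupffer cell and macrophage markers 16 were lower, including Hmox1 (-1.69), Lyz2 (-2.18) and Cd5l (-2.22), and 1 was higher, the haemoglobin scavenger receptor Cd163 (1.14); adjusted over the list alone 17 were lower and 1 higher (adjusted p = 1.17e-08; adjusted p = 0.323 with an estimated correlation). Cyp3a16 and Cd163 were picked out here after their values were seen. Of 17 inflammatory genes 11 were lower and 1 higher, 12 lower and 1 higher adjusted over the list alone (adjusted p = 0.000111; adjusted p = 0.236 with an estimated correlation). Of 22 antigen presentation genes 12 were lower, including H2-K1 (-3.17), and 3 higher, including H2-Ea-ps (3.67), 15 and 3 adjusted over the list alone; genes of this polymorphic locus differ in sequence between strains (adjusted p = 0.00154; adjusted p = 0.513 with an estimated correlation).

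Of 20 ketogenesis and PPARA-regulated genes 12 were higher and 0 lower in limma, including Mgll (1.41), a lipase, Fabp1 (1.16) and Vnn1 (1.69), and 13 adjusted over the list alone (median 0.45, adjusted p = 0.000352; adjusted p = 0.382 with an estimated correlation). Of 23 tricarboxylic acid cycle genes 10 were higher, including Aco1 (0.78) and Cs (0.75), and 11 adjusted over the list alone (adjusted p = 0.00181; adjusted p = 0.48 with an estimated correlation). Of 18 lipid droplet and lipase genes 9 were higher and 2 lower, the latter including lipoprotein lipase, Lpl (-1.32), and 10 and 2 adjusted over the list alone (adjusted p = 0.0235; adjusted p = 0.323 with an estimated correlation). In all, 15 of 55 lists were called, 5 higher and 10 lower, and 0 with an estimated correlation in camera, where fry called 28. The count was 2174 among the 8 libraries with few genes at 1 fragment.

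The comparison of the strains after hyperoxia asked how the livers differed at the end of the exposure. BALBc livers expressed more of Acaa1a and Acaa1b, enzymes of fatty acid oxidation in peroxisomes, of Cpt1a and Etfdh, which serve it in mitochondria, and of Slc4a1 and Rhd, genes of red cells and their precursors. The thioesterases Acot2 and Acot1, which release fatty acids from coenzyme A, were higher by 2.11 and 2.10 on the log2 scale. The mitochondrial genome transcripts mt-Cytb and mt-Nd6 were lower in BALBc. Hamp did not pass between the strains (124 ± 63.7 FPKM in C57, n = 4, and 257 ± 127 in BALBc, n = 4; adjusted p = 0.212).

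After hyperoxia 3025 genes passed, 1549 higher and 1476 lower in BALBc, 525 of them by at least 2-fold. Serpina3k was higher by 4.34 ± 0.39 (adjusted p = 1.18e-06), Prg2 by 3.33, the carboxylesterase Ces1f by 3.25, C1s2 by 3.03, Eno1b by 2.99, Lrrc24 by 2.97 and Slc4a1, the red cell anion exchanger, by 2.77. Lower in BALBc were Rpl29 (-5.99), Rps2 (-5.25), Rps18 (-4.84), Rpl30 (-3.88), the mitochondrial transcript mt-Nd3 (-3.89), the lipase-related gene Pnliprp1 (-3.72) and Serpina1e (-3.45), an antitrypsin gene of a near-identical family. Marco stayed lower, at -2.50 ± 0.25 (adjusted p = 3.58e-06).

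Of 19 genes of peroxisomal and microsomal fatty acid oxidation 15 were higher in BALBc, including the thiolases Acaa1a (1.14) and Acaa1b (1.19) and Pex11a (1.09), and Cyp4a31 (-1.83) was lower, with the same counts adjusted over the list alone (median 0.74, adjusted p = 1.63e-08). Of 19 mitochondrial fatty acid oxidation genes 12 were higher, including Cpt1a (0.64), which admits fatty acids to mitochondria, Etfdh (0.69) and Acadvl (0.63), and 13 adjusted over the list alone (adjusted p = 7.67e-07). Of 20 ketogenesis and PPARA-regulated genes 14 were higher and 1 lower, with the same counts adjusted over the list alone (median 0.62, adjusted p = 1.77e-08). Plin2, which coats lipid droplets, was higher by 1.10 and the pantetheinase Vnn1 by 1.87. Of 15 genes of polyunsaturated fatty acid desaturation and elongation 9 were higher, including Fads2 (0.92), and 1 lower, Fads6 (-0.92), and adjusted over the list alone 10 and 2 (adjusted p = 0.000144). For each of these 4 lists the call was lost with an adjusted p = 0.114 with an estimated correlation. Of 18 lipid droplet and lipase genes 9 were higher and 1 lower, 11 and 1 adjusted over the list alone (adjusted p = 2.57e-06; adjusted p = 0.0764 with an estimated correlation). Of 24 cholesterol synthesis genes 15 were higher, including Hmgcs1 (1.23), Fdft1 (0.51) and Nsdhl (0.96), and 1 lower, Sc5d (-0.71), 17 and 1 adjusted over the list alone (adjusted p = 5.8e-06; adjusted p = 0.327 with an estimated correlation).

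Of 26 erythroid markers 16 were higher in BALBc after hyperoxia, including Slc4a1, Rhd (1.91) and Hemgn (1.89), and 17 adjusted over the list alone (median 0.90, adjusted p = 8.69e-08). Of 13 mitochondrial genome transcripts 10 were lower, over all genes and adjusted over the list alone, including mt-Cytb (-1.80) and mt-Nd6 (-1.38) (median -1.38, camera adjusted p = 7.74e-08). The mitochondrial genome held 4.24% to 4.94% of fragments in C57 hyperoxia, all of the class with many genes at 1 fragment. In BALBc hyperoxia 1, of the same class, it held 3.69%, and in the other BALBc hyperoxia libraries 2.89% to 3.12%. Library class may thus account for part of this difference. Of 20 Kupffer cell and macrophage markers 14 were lower and 1, Cd163 (1.24), higher, with the same counts adjusted over the list alone (adjusted p = 2.57e-06). For these 3 lists the call was lost with an adjusted p = 0.271 with an estimated correlation. In all, 21 of 55 lists were called, 10 higher and 11 lower, and 0 with an estimated correlation in camera, where fry called 34.

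The strain differences in normoxia and hyperoxia were similar, with Pearson's r of 0.778 across genes, which are not independent replicates. There were 1094 genes higher in BALBc under both conditions, where independent lists would share 238.55, and 998 lower under both, where 215.75 would be shared; 12 genes passed in opposite directions. With library class as a term the count after hyperoxia was 1935, and among only the 7 libraries with many genes at 1 fragment, which leave 1 BALBc hyperoxia library, 1297.

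The median, mean and test of a list differed in sign for the following lists, and no such list was called. In C57 these were iron and haem metabolism (median -0.05, mean 0.06), the acute phase response (median 0.06, mean 0.06, test lower, adjusted p = 0.921), lipoproteins, endoplasmic reticulum chaperones, CAR and PXR targets, complement, T and NK cells, sinusoidal endothelium, cholangiocytes and adipose tissue. In BALBc they were hypoxia-inducible factor targets, the acute phase response (median -0.09, mean 0.16, adjusted p = 0.0544), p53 targets, the circadian clock, immediate early genes and B cells. For the interaction they were lipoproteins, the respiratory chain, growth regulation, the acute phase response, T and NK cells, sinusoidal endothelium, cholangiocytes and adipose tissue. Between the strains they were lipoproteins, p53 targets and late-maturing hepatocyte genes under both conditions, platelet markers, stellate cells and sex-linked genes in normoxia, and serine and folate metabolism, steroid metabolism and AHR targets in hyperoxia.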

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

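The splits of the libraries were planned. The tests of library complexity, the share of Kupffer cells, ribosomal gene copies, pseudogene families, separate alignment and hepcidin were chosen only after the result was seen.

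Of 159 groups of 4 libraries tested for a library far from the others, 10 had one. The rule compared the gap between a library and its nearest neighbour with the range of the group. Its limit was meant to flag about 1 in 20 groups of normally spread values, a rate not checked on these data. Many of these flags may thus be chance, but the number of genes at 1 fragment in C57 normoxia 4 belongs to the library class described above. Leaving out C57 normoxia 4 or BALBc hyperoxia 1, the libraries with 3 each, gave 237 called genes in C57 and 69 in BALBc. The values, in FPKM with the range of the other libraries, were Fabp4 in C57 hyperoxia 3 (3.57 against 2.64 to 2.79), Hamp in BALBc hyperoxia 1 (67.8 against 302 to 339), Igfbp1 in BALBc hyperoxia 3 (231 against 184 to 191), Tfrc in BALBc hyperoxia 1 (23.9 against 12.7 to 13.5), Afp in BALBc hyperoxia 1 (58 against 37.5 to 40.1), Ppbp in C57 normoxia 1 (4.25 against 9.13 to 9.99), Cyp2b10 in C57 normoxia 4 (2.36 against 0.147 to 0.439) and C1s2 in C57 hyperoxia 4 (0.0931 against 0.0236 to 0.0252). BALBc hyperoxia 1 had less Hamp and more Tfrc than the other 3 libraries of its group. C57 normoxia 4 had a denominator of 1.527e+07 fragments against 1.609e+07 to 1.617e+07, and 2192 genes at 1 fragment against 205 to 247 in the other C57 normoxia libraries.

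The oxygen response differed between the strains by the interaction test for 107 genes. Among named genes the response was higher in BALBc for Hamp (3.91), Afp (2.65), Marco (2.28, called lower in C57 and not called in BALBc), Cyp4a10 (1.93), Ppbp (1.76), Acot3 (1.72), Tlr2 (1.70, likewise lower in C57 alone) and Igfbp1 (1.67). It was lower for Serpina3k (-3.21), Mug1 (-2.32), Mug2 (-2.02), Cyp4f14 (-1.99), Thrsp (-1.66, near 0 FPKM in C57 under both conditions), Cyp2c70 (-1.48) and Prodh (-1.47). Of 55 lists 31 were called, and only 2 of them with an estimated correlation, the platelet markers and the hypoxia-inducible factor targets. Lists with a higher response in BALBc, by their median log2 difference, were platelet markers (0.702), erythroid markers (0.587), neutrophil precursors (0.537), fetal liver genes (0.471), inflammatory genes (0.4), peroxisomal and microsomal fatty acid oxidation (0.398), Kupffer cells (0.259), cholesterol synthesis (0.248), lipid droplets and lipases (0.232), polyunsaturated fatty acids (0.196), mitochondrial fatty acid oxidation (0.193), hypoxia-inducible factor targets (0.176), phospholipids (0.13), ketogenesis and PPARA-regulated genes (0.117), iron and haem (0.0699) and NRF2 targets (0.041). Lists with a lower response were mitochondrial genome transcripts (-0.683), the urea cycle (-0.514), cell cycle (-0.278), serine and folate metabolism (-0.238), pericentral genes (-0.234), late-maturing hepatocyte genes (-0.234), CAR and PXR targets (-0.216), interferon-stimulated genes (-0.203), amino acid catabolism (-0.197), endoplasmic reticulum chaperones (-0.197), bile acids (-0.195), cytosolic heat shock (-0.18), steroids and retinoids (-0.176), periportal genes (-0.139) and complement (-0.0821).

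Some of these list calls were lost on leaving out 1 library, given here with the highest adjusted p reached. These were NRF2 targets without C57 normoxia 3, C57 hyperoxia 1, 3 or 4, BALBc normoxia 2 or BALBc hyperoxia 4 (0.256), periportal genes without C57 normoxia 2, C57 hyperoxia 4, BALBc normoxia 3 or BALBc hyperoxia 1 (0.123), bile acids without C57 normoxia 4, C57 hyperoxia 1 or BALBc normoxia 3 (0.12), CAR and PXR targets without C57 normoxia 4, BALBc normoxia 1 or BALBc hyperoxia 3 (0.0887), and phospholipids without C57 normoxia 3, BALBc normoxia 1 or BALBc hyperoxia 4 (0.0863). With 2 or fewer such libraries these were ketogenesis and PPARA-regulated genes without C57 hyperoxia 4 or BALBc normoxia 3 (0.143), neutrophil precursors without C57 normoxia 4 or BALBc normoxia 2 (0.129), lipid droplets without BALBc normoxia 1 or BALBc hyperoxia 2 (0.0702), interferon-stimulated genes without C57 normoxia 2 or C57 hyperoxia 4 (0.0659), complement without C57 normoxia 2 (0.0893), and iron and haem without BALBc normoxia 3 (0.0501).

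In none of the 5 comparisons did another split give as many genes as the real one. The real split is itself counted, so 1 of 35 (1 of 100 for the interaction) was the lowest share possible. That makes chance unlikely without excluding it. In C57 the real split also largely separates the 2 library classes, which the splits cannot tell from oxygen. In C57 1 of 35 splits of the libraries gave as many genes as the real 122, which was the real split itself, and the highest other gave 5. In BALBc it was 1 of 35 (123, highest other 1), for the interaction 1 of 100 drawn (107, highest other 39), between strains in normoxia 1 of 35 (3910, highest other 1797) and in hyperoxia 1 of 35 (3025, highest other 2). The split with 1797 genes set C57 normoxia 3 with the 3 BALBc normoxia libraries.

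The C57 oxygen response coincides in part with the class of libraries with many genes at 1 fragment, and macrophage genes such as Marco and Lyz2 fell. A difference in complexity, with fewer genes seen in the other class, was looked for in the called genes between the classes among BALBc libraries. The median movement there was 0.0722 of the C57 change (-0.000508 to 0.128 over leave-one-out refits, quartiles -0.0326 to 0.193), with 82 of 122 genes moving the same way. By the slope on the number of weakly expressed genes it was 0.0844 (-0.00864 to 0.3). The classes lay closer together in BALBc, however. Libraries with few genes at 1 fragment held 2835 to 5162 genes at 1 to 10 fragments in BALBc and 1112 to 2260 in C57. The other class held 6648 to 7127. The slope assumes that the BALBc relation holds at the lower C57 numbers, so neither value can exclude complexity as the cause in C57. With the class as a term the median absolute log2 change of the 122 genes was 0.505 (median SE 0.129) against 0.538 (0.106). The size changed little while the error grew, and 14 genes passed. All 122 kept their sign, but the called genes did so in every alternative fit, so the sign cannot tell class from oxygen. Nor can the class term draw on C57 hyperoxia, where all 4 libraries were of 1 class. A loss of Kupffer cells lowers all their markers, but over the 20 measured markers the median log2 change was -0.33 (-0.408 to -0.195 over leave-one-out refits) with quartiles of -0.685 to 0.0758 and 7 above 0, so a lower share of these cells and a change in their state cannot be told apart. Only 1 C57 normoxia library was of that class, so a class effect specific to C57 remains open, as does an effect of oxygen.

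Some ribosomal protein genes were far lower in BALBc, and reads of BALBc transcripts could have been assigned to pseudogene copies. For the 7 genes at least 4-fold lower, the copies gained in 5 and not in 2 (Rps18 and Rpl21, the latter with -0.8315), the median gain was 0.1243 of the parent's C57 level (0.1 or more in 4 genes, highest 0.5549 for Rpl26), and for the other 76 ribosomal genes it was -0.009208 (one-sided permutation test, p = 0.00046 with 1e+05 permutations). In the test made before that, over 27 families of 33 pseudogenes at least 4-fold higher in BALBc (30 matched), the parent's change over that of its copies had a median of -1.099, with quartiles of -2.479 to 0.2507, and the parent was lower in 18. The spread of both tests leaves shared reads open. Strain sequence and a separate alignment of 1 strain cannot be told apart, since the genes were low in all 7 BALBc libraries, and a biological strain difference stays open and untested.

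Hamp and Hamp2 rose after hyperoxia, Hamp more so in BALBc. Among BALBc libraries with few genes at 1 fragment, the lowest of 3 hyperoxia libraries lay 6.97 above the highest of 2 normoxia libraries for Hamp on the log2 scale (3.45 for Hamp2), which argues against complexity as the source of the rise in BALBc. For the larger rise in BALBc it stays open, since the single BALBc libraries of the other class differed by only 4.23, and the strain difference in the Hamp response of 3.91 (SE 0.752) was 3.54 (SE 0.863) with class as a term, a lower value with a larger error that lost its call (adjusted p = 0.104). With Xist as a covariate the difference was 3.85 (SE 0.686), and of 22 other acute phase genes 4 changed by more than 0 in BALBc with a median of -0.0953, which argues against sex composition and a general acute phase response. Hamp also started lower in BALBc, at 1.11 to 2.68 FPKM in normoxia against 8.49 to 31.8 in C57. In hyperoxia the strains overlapped (67.8 to 339 FPKM in BALBc, 59.7 to 212 in C57). The larger rise in BALBc thus cannot be told from its lower starting level. A strain difference in the response of iron regulation to oxygen stays a hypothesis, found and tested on the same data. Reads shared between Hamp and Hamp2 were not tested.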

How the results depend on the processing

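Library class as a term, the covariate for weakly expressed genes, the fits to 1 class of libraries and the fit without shared-read features were tests chosen after seeing the data; the other alternatives and the leave-one-out fits were fixed before the data were examined. Of 15961 alternative values for 545 named gene results, 14313 stayed on the same side of the threshold with the same direction, 1648 kept the direction but not the call, and 0 reversed in limma. All 545 were chosen for passing in the same data, which makes a reversal unlikely. Most were strain comparisons, where 180 of 202 in normoxia and 191 of 207 in hyperoxia passed whichever library was left out. That held for 19 of 35 in C57, 13 of 57 in BALBc and 15 of 44 for the interaction. Of 2420 values for 110 list results, 2134 stayed, 285 lost the call and 1 reversed. The reversed value was that of the respiratory chain list in BALBc under quantile normalization (camera adjusted p = 0.948), for a cause that was not tested. In the same setting 93 list results stayed and 16 lost the call. The 122 genes called in C57 fell to 70 with no filter, 74 with no variance trend and 79 with the replicate block (no pairing was found). They fell to 67 with the Xist covariate, 47 with array weights and 20 with only the groups compared. The count was 14 with library class as a term and 12 with the covariate for weakly expressed genes. With only the groups compared, the count was 130 in BALBc and 4013 between strains in hyperoxia, both above the main counts. Between strains in normoxia it fell to 2242. These fits also leave out groups whose spread differed, so they cannot tell whether fewer libraries account for the fall to 20 in C57. Array weights, lower for noisier libraries, were 0.356 to 0.709 in C57 normoxia and 1.58 to 1.9 in C57 hyperoxia. The 123 in BALBc fell to 78 with no filter and to 12 among the 8 libraries with few genes at 1 fragment. The 107 of the interaction fell to 29 with no filter, 67 with the replicate block and 48 with array weights. They fell to 28 with library class as a term and 17 with the covariate for weakly expressed genes. The strain difference in normoxia fell from 3910 to 1092 among the 7, 2174 among the other 8 and 2242 with only the groups compared, and that in hyperoxia from 3025 to 1935 with library class as a term and 1297 among the 7. With no filter more genes are adjusted for, and with library class as a term the median SE of the genes called without it grew from 0.106 to 0.129 in C57, from 0.183 to 0.209 for the interaction and from 0.114 to 0.135 between strains in hyperoxia, and their median absolute log2 values went from 0.538 to 0.505, from 1.02 to 1.01 and from 0.528 to 0.498. The cause of the other shifts was not tested. The 7 libraries with many genes at 1 fragment hold 4 C57 hyperoxia libraries and 1 of each other group. Their spread comes from C57 hyperoxia alone, so the number of genes passing there says little about the calls. Leaving out 1 library gave 36 to 237 genes in C57, 24 to 156 in BALBc, 40 to 162 for the interaction, 3006 to 3866 between strains in normoxia and 2421 to 3310 in hyperoxia, and a correlation between the responses of -0.01151 to 0.07375. C57 counts outside 1.5-fold were 62 and 237 without C57 normoxia 2 and 4, 36, 46, 46 and 45 without C57 hyperoxia 1 to 4, 76 without BALBc normoxia 2 and 75 without BALBc hyperoxia 3; BALBc counts were 53 and 24 without BALBc normoxia 2 and 3, and 69, 56, 63 and 66 without BALBc hyperoxia 1 to 4; interaction counts were 162 without C57 normoxia 4, 45 and 53 without C57 hyperoxia 2 and 4, 47 and 44 without BALBc normoxia 2 and 3, and 40, 50 and 48 without BALBc hyperoxia 2 to 4. Under quantile normalization 36 of the C57 calls were higher and 52 lower. Only 1 class was left in some groups of the fits to 1 class, so the fit to the 8 libraries gives no value for C57 hyperoxia, the interaction or the strain difference in hyperoxia. Denominators of 1.49e+07 to 1.91e+07 fragments limit genes of few fragments, and libraries with like denominators differed in how many such genes they held.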

Other observations

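The tests of ribosomal protein genes after hyperoxia and of the maturation index were chosen only after the result was seen. Of 83 ribosomal protein genes, 13 fell in C57 after hyperoxia in limma, and 77 had values below 0, with a median of -0.30 (camera p = 3.38e-31, 0.019 with an estimated correlation). With library class as a term the median was -0.42 in C57 and 0.05 in BALBc. In BALBc 30 of the 83 values lay below 0, with a median of 0.04, and the list did not pass (camera p = 0.165, 0.749 with an estimated correlation). The interaction had a median of 0.35 (camera p = 1.02e-21, 0.0448 with an estimated correlation).

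In BALBc, hyperoxia also raised Igfbp2 (1.12), Osgin1, a target of the oxidant sensor NRF2 (0.78), and Lpcat3, which remodels phospholipids (0.50). Saa4, a constitutive serum amyloid, fell by 0.86 on the log2 scale, and Ahcy, which forms homocysteine from S-adenosylhomocysteine, fell by 0.53. Neutrophil precursor markers were called higher there as a list, with 13 of 16 values above 0 and no single gene passing (adjusted p = 0.0171, and 0.387 with an estimated correlation). That call was lost without BALBc normoxia 2 or hyperoxia 4 (highest adjusted p = 0.367). The call of Lpcat3 was lost in 1 of 15 leave-one-out refits, as was that of Igfbp2.

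An index of 19 late-maturing minus 14 fetal liver genes changed by 0.3011 in C57 after hyperoxia (exact permutation test, p = 0.1429) and by -0.3419 in BALBc (exact permutation test, p = 0.02857). The difference between the strains was -0.6431 (exact permutation test over 2450 relabelings, p = 0.00449). Both lists had already been called in the interaction, with medians of -0.234 and 0.471, so the index restates that observation and tests no cause. The C57 change alone did not pass, which leaves open whether the strains move in opposite directions. Among libraries with few genes at 1 fragment the BALBc change was -0.3017.

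Xist was above an FPKM of 1 in 2 of 4 C57 normoxia, 1 of 4 C57 hyperoxia, 2 of 3 BALBc normoxia and 2 of 4 BALBc hyperoxia libraries. BALBc normoxia 1 (Xist 55.9, Ddx3y 0.764 FPKM) and BALBc hyperoxia 4 (66.2 and 0.958) had high Xist with a low signal of the Y-linked Ddx3y.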
